A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

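RNA of 8 samples of Saccharomyces cerevisiae was sequenced, 2 in each of 4 groups: strain U and strain S at 6 h and at 12 h. Per the labels, cells were grown in 10 mL of YPD medium with 2% glucose in flasks of 50 mL, from an OD600 of 0.5, at 30 °C with shaking at 170 rpm. Total RNA was extracted with hot phenol, libraries were made with a stranded mRNA kit, and sequencing was paired-end with 100 cycles. The deletions that the labels give for GCR1 are 1 to 574 in U and 4 to 742 in S. How these positions are counted is not given in the sources used here.

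The deposited values are FPKM made by the authors, a value scaled to gene length and library size, 1 value per gene and library, rounded to at most 2 decimals. The submitters list bcl2fastq 1.8.2, FastQC 0.10.1, TopHat2 2.1.1 and Cufflinks with the build sacCer3. The version and settings of Cufflinks and the annotation are not given in the sources used here. Library sums of FPKM ran from 1504396 to 1548312 and medians from 38.8 to 51.3. The depth per sample is unknown, so the precision of a value and the limit behind a value of 0 are unknown too. Of 7126 rows, 6048 were matched to the R64 annotation by locus tag and 114 by symbol, and 964 were not matched. Of all rows, 606 were 0 in every library. Of the rows with a mean of at least 10 FPKM, 49 were listed at 0 in some library. 31 of these were among the 208 rows of this level shorter than 300 bp, while 3 of the 5256 longer rows were listed at 0.

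The values were analysed as log2(FPKM + 1) without further scaling, for the 6339 rows with a mean of at least 1 FPKM over the 8 libraries. One fit of limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend, in R 4.3.3) to the 4 groups gave 5 comparisons: S minus U at 6 h and at 12 h, 12 h minus 6 h in U and in S, and the difference of these time changes. The groups shared 1 estimate of the spread because each had 2 libraries, with 4 residual and 2.33 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes were called at an adjusted p under 0.05. Errors of fold changes are standard errors of the fit. Tables were prepared with Python 3.11.15 and pandas 2.3.3. With 2 libraries against 2, chance gives groups that do not overlap for 33.3% of genes. The share was 10.7% for the strains at 6 h and 20.6% at 12 h, below chance, and 81.1% and 79.9% for the times in U and S.

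37 gene lists were fixed before the data were examined, as were the comparisons, the tests and the settings listed first in the last paragraph. 34 lists had at least 3 tested members. Each was tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and with an estimated correlation as the alternative, which called 0 lists in every comparison. The preset value takes members as nearly independent. Members of some lists moved together between replicates: 0 of 49 ribosome biogenesis genes were higher in replicate 1 in either 6 h group. The p-values with the preset correlation can thus be far too small and do not measure the spread between libraries. Members were also counted when adjusted over the list alone. A list's value is the median log2 fold change of its tested members. The genes named were chosen by a rule: per comparison the 10 highest and 10 lowest log2 fold changes among genes called with an absolute value of at least 1, a mean of at least 10 FPKM in the higher group and both libraries of the higher group above both of the lower; GCR1 and GCR2; and up to 4 members of each list described, called members first. Members of the lists of glycolysis and of regulators of carbon metabolism could be named in every comparison.

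The analysis was tested on simulated data, in which 200 of the 6339 genes were changed between the strains with the spread of these libraries. At 12 h it called 49.3%, 91.0% and 98.5% of genes changed by 1, 2 and 3 on the log2 scale, with 6 calls among unchanged genes. At 6 h it called 41.8%, 86.6% and 92.4%, with 4. The noise was drawn independently for each gene and library, without the differences between replicates that U and S share. These shares hold for that noise and for 200 changed genes. They are no rate for these libraries, where a gene that was not called may still differ. A list raised by 1 had adjusted p = 0.0174 at 12 h with an estimated correlation, and 0 unchanged lists were called. The genes of a list did not vary together in this simulation. It therefore does not show how the list tests behave when genes are correlated.

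The settings fixed before were another pseudocount, no filter and a stricter filter, median-of-ratios scaling, quantile normalization, the replicate number as a block, no trend, a fit to the groups compared alone, each library left out in turn and a minimum fold change. Added after seeing the data were a block within each time, leaving out rows listed at 0, leaving out both 6 h libraries of replicate number 1, keeping only matched rows, leaving out each library in turn in the list tests, and a self-contained list test (fry). The replicate numbers are not stated to pair the samples. Their differences between replicates 1 and 2 correlated across genes at 0.64 between the 6 h groups, 0.38 between the 12 h groups and at most 0.08 across times. The main fit counts such shared differences as spread. Between the strains it had 56 genes at 6 h and 61 at 12 h at an unadjusted p under 0.05. With the block within each time limma had 247 and 256. A strain difference that was not called is thus not shown to be absent.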

Results

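Transcripts were measured by RNA sequencing in budding yeast of the BY4741 background that made 1 of 2 forms of Gcr1, a transcription factor known as an activator of glycolytic genes. The labels name the forms Gcr1(U) and Gcr1(S) and tie them to the processing of the intron of GCR1. Strain U (JHY9100) made Gcr1(U) and strain S (JHY9200) made Gcr1(S). Cells grown in glucose medium were sampled at 6 h, which the labels call exponential phase, and at 12 h, after the diauxic shift, when glucose is used up and cells turn to ethanol. Each of the 4 groups had 2 libraries, 8 in all. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between samples. In the comparisons of the strains this spread also holds differences between replicates 1 and 2 that U and S shared.

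The deposited table listed FPKM values for 7126 rows in each library, and the sums per library ran from 1504396 to 1548312. The read depth is unknown, so a value listed at 0 has no detection limit. Time separated the libraries most, with 84.0% of the variance on the first principal component. At 6 h the libraries of each group stood apart. Targets of the heat shock factor, which encode chaperones, had a median log2 difference of 2.08 between replicates 1 and 2 of U and 1.98 in S, with all 19 members higher in replicate 1 in both strains. At 12 h the same differences were 0.13 and 0.04. The general stress list (1.52 in U and 2.31 in S) and the trehalose and glycogen list (1.42 and 1.89) were also higher in replicate 1 at 6 h, and ribosome biogenesis was lower (-0.63 and -0.85).

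**Figure D1:**
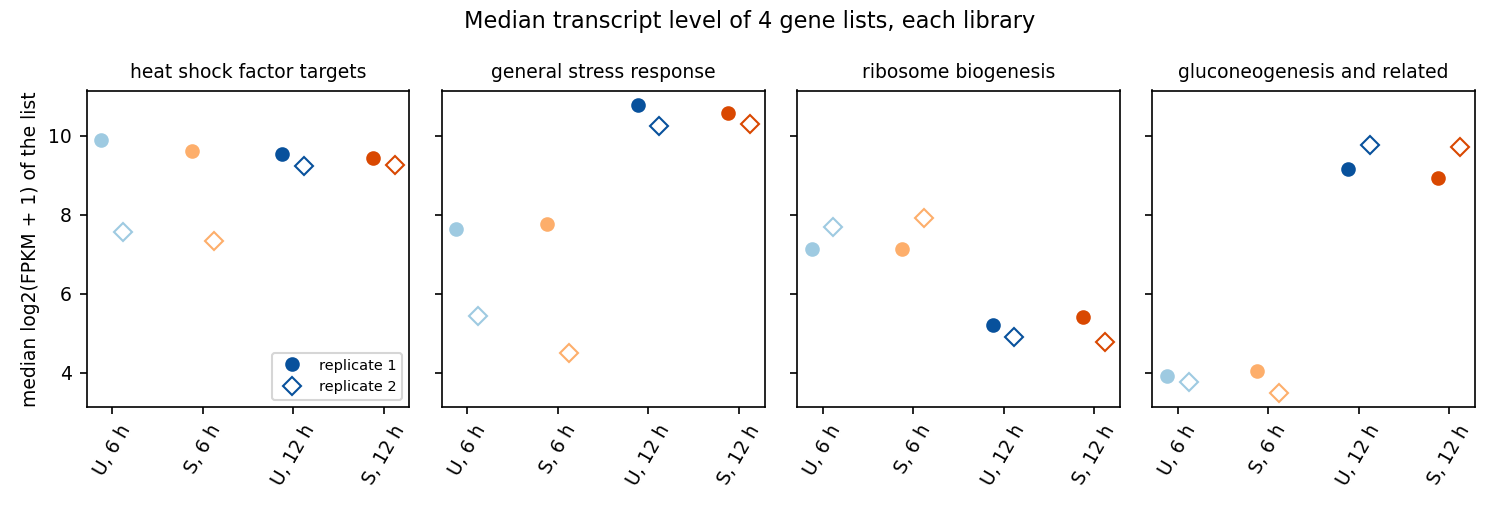
Median log2(FPKM + 1) of the members of 4 gene lists in each library (filled circles, replicate 1; open diamonds, replicate 2; 2 libraries per group). The heat shock factor targets of the 6 h replicate 1 libraries lie above those of replicate 2, by a median difference of 2.08 in U and 1.98 in S.

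The comparison of the strains at 12 h asks how the transcriptomes differ between the Gcr1 forms after the diauxic shift. The glycolysis list, 17 genes from the hexokinases to pyruvate kinase, was called higher in S than in U, with 5 of 17 members called and adjusted p = 0.0783 with an estimated correlation. Its median log2 fold change was 1.87 (3.66-fold), with 16 of 17 members above 0. CDC19, the main pyruvate kinase, stood at 397 ± 26.4 FPKM in S and 33.6 ± 10.8 in U (SD, n = 2 each), a log2 fold change of 3.56 (SE 0.23, adjusted p = 0.00877). TDH3, a glyceraldehyde-3-phosphate dehydrogenase, reached 11684 ± 1171 FPKM in S and 1628 ± 206 in U (SD, n = 2 each), a log2 fold change of 2.84. PDC1 and ADH1, the main enzymes of ethanol formation, had log2 fold changes of 1.98 (adjusted p = 0.0776) and 2.50 (adjusted p = 0.0807), which did not pass the test. With a block of replicate number within each time, chosen after seeing the data, PDC1 passed (adjusted p = 0.0335), as did ADH1 with quantile normalization (0.0358), while TDH3 did not pass with quantile normalization (0.109) or with a single block of replicate number (0.0636).

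**Figure D2:**
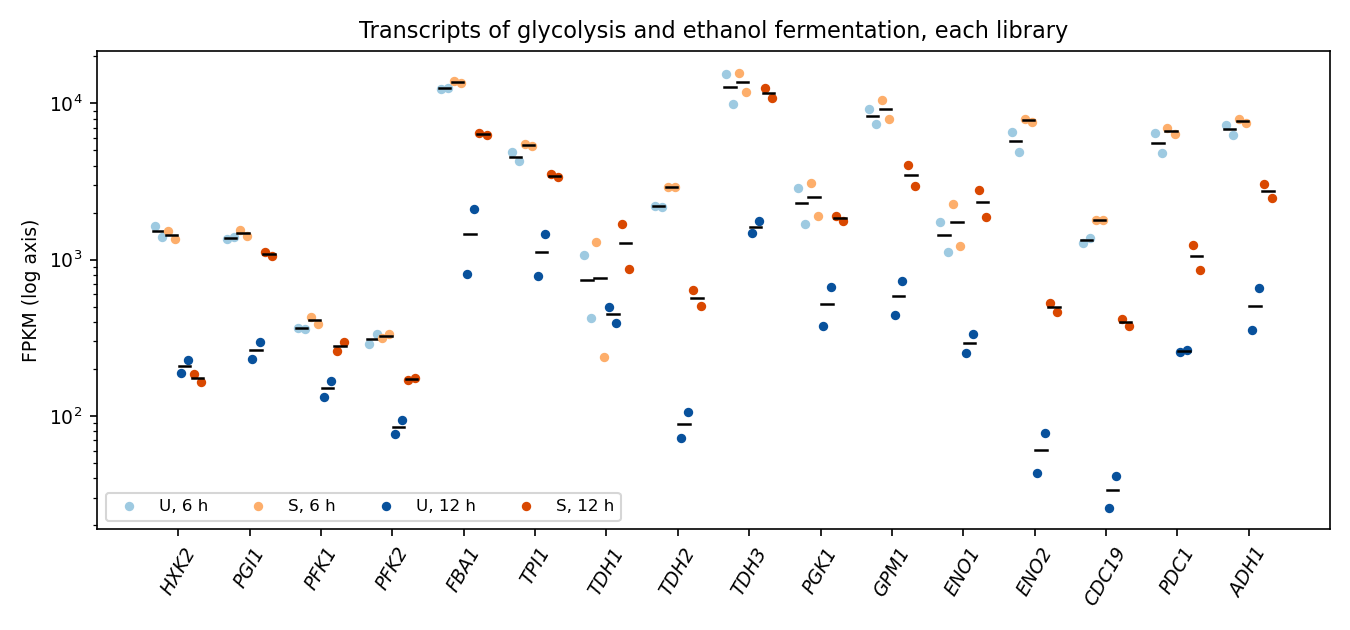
FPKM (log axis) of 14 genes of glycolysis and of PDC1 and ADH1 in each library (points, 2 libraries per group; black lines, group means). At 12 h both S libraries lie above both U libraries for each gene drawn except HXK2. The other members of the list of 17 glycolysis genes, HXK1, GLK1 and PYK2, are not drawn.

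Of 6339 genes tested with limma, 8 differed between the strains at 12 h, 7 higher and 1 lower in S. Besides CDC19 and TDH3, the higher genes were ENO2 (enolase, log2 fold change 3.07, adjusted p = 0.0306), TDH2 (2.67, adjusted p = 0.019), PGI1 (phosphoglucose isomerase, 2.04, adjusted p = 0.019), YAL037C-B (3.56, adjusted p = 0.0159) and YCR038W-A. The sequences of TDH2 and TDH3, and those of ENO1 and ENO2, are alike, so reads may be shared within these pairs, which was not tested, and YAL037C-B overlaps CDC19. The split within each pair is uncertain. YCR038W-A was listed at 0 in both U libraries and at 33.7 FPKM on average in S. SNR128, a small nucleolar RNA, was listed at 0 in both S libraries and at 18.2 and 45.7 FPKM in U. Whether the values of 0 of YCR038W-A and SNR128 were failed estimates was not tested. Without rows listed at 0 in any library, a setting chosen after seeing the data, limma called 6 genes (51 at an unadjusted p under 0.05). All were higher in S. CDC19 (YAL038W) lies on chromosome I from 71786 to 73288, TDH3 (YGR192C) on VII from 882812 to 883810, ENO2 (YHR174W) on VIII from 451327 to 452640, TDH2 (YJR009C) on X from 453683 to 454681 and PGI1 (YBR196C) on II from 612236 to 613900 of the R64 assembly.

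Of the 17 glycolysis genes, 5 were called higher at 12 h over all genes and 12 when adjusted over the list alone. The members outside the calls over all genes included ENO1 (log2 fold change 2.98, adjusted p = 0.0959, and 0.028 with the block within each time), GPM1 (2.59, adjusted p = 0.0776), FBA1 (2.29) and PFK2 (1.02), while HXK2, a hexokinase, had -0.25. The list had adjusted p = 5.84e-81 with the preset correlation and adjusted p = 0.0783 with an estimated correlation. The first takes the members as nearly independent and is no measure of the spread between libraries. In a self-contained test (fry), chosen after seeing the data, the glycolysis and ethanol fermentation lists had a false discovery rate of 0.0947 for a change in 1 direction. For changes in either direction fry gave 0.00525 for glycolysis and 0.00643 for ethanol fermentation, which does not say which way the members changed. With camera the ethanol fermentation list was called higher (adjusted p = 7.04e-06, and adjusted p = 0.108 with an estimated correlation) on a median of 0.0076 and a mean of 0.53, with 2 of 8 members, PDC1 and ADH1, called when adjusted over the list alone. Of the genes called over all genes, TDH3 kept its call in 0 of the 8 fits that left out 1 library, ENO2, TDH2 and PGI1 in 1 each and CDC19 in 4. The log2 fold changes stayed above 0 in these fits. They ran from 3.23 to 3.88 for CDC19, 2.72 to 2.97 for TDH3 and 2.65 to 3.49 for ENO2. For TDH2 they ran from 2.40 to 2.95 and for PGI1 from 1.86 to 2.22. With a single block of replicate number CDC19 alone of the 17 glycolysis genes kept its call. TDH3, TDH2 and PGI1 (adjusted p = 0.0636 each), ENO2 (0.0921), YAL037C-B (0.0595) and SNR128 (0.078) lost theirs. The adjusted p of CDC19 was 0.0521 without U 6 h replicate 1, 0.0526 without U 6 h replicate 2, 0.0576 without S 12 h replicate 1 and 0.127 without S 12 h replicate 2, and the highest of TDH3 was 0.255, without S 12 h replicate 1. ADH1 and FBA1 were called without U 12 h replicate 2 (adjusted p = 0.0147 and 0.00285), and GPM1 and PFK2 with the block within each time without rows listed at 0 (0.032 and 0.0252). The count of 8 became 1 without U 6 h replicate 1, 1 without U 6 h replicate 2, 4 without U 12 h replicate 1, 15 without U 12 h replicate 2, 2 without S 6 h replicate 1, 2 without S 6 h replicate 2, 7 without S 12 h replicate 1, of which 1 was among the 8, and 1 without S 12 h replicate 2, and limma called 0 genes (103 at an unadjusted p under 0.05) in a fit to the 12 h libraries alone.

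4 lists were called lower in S at 12 h, each with small differences. The 10 histone genes were all below 0, with a median of -0.17 (adjusted p = 6.78e-05, and adjusted p = 0.237 with an estimated correlation), HTA2 at -0.50 and HTB2 at -0.45. Small nucleolar and ribosomal RNA had a median of -0.28 (adjusted p = 3.94e-05), translation factors -0.14 (adjusted p = 0.0413) and cytosolic ribosomal proteins -0.11 (adjusted p = 0.00532), each with adjusted p = 0.999 with an estimated correlation. Of the members of these 4 lists, SNR128 alone was called, which belongs to the RNA list. That list was fixed as a sign of the selection of poly(A) RNA, so its difference may reflect the libraries and not the cells. Leaving out 1 library ended each call: the adjusted p was 0.152 for histones and 0.111 for translation factors without U 12 h replicate 1, 0.282 for translation factors and 0.0555 for the RNA list without U 12 h replicate 2, 0.155 for translation factors and 0.156 for ribosomal proteins without S 12 h replicate 1, and 0.183 for histones and for translation factors without S 12 h replicate 2. Without U 12 h replicate 2 the ribosomal proteins were higher in S instead (adjusted p = 7.6e-22), and without both 6 h libraries of number 1 their adjusted p was 0.194.

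GCR1 itself, on chromosome XVI from 412254 to 415362 with an intron from 412262 to 413012, stood at 96.7 ± 10.8 FPKM in S and 31.6 ± 1.90 in U at 12 h (SD, n = 2 each). Its log2 fold change of 1.58 (SE 0.42) did not pass the test (adjusted p = 1, unadjusted p = 0.00804), and GCR1 was called with the block within each time without rows listed at 0 (adjusted p = 0.0373). At 6 h it was listed at 143 and 58.9 FPKM in S and at 60.9 and 40.2 in U, a log2 fold change of 0.88 (SE 0.42) that ran from 0.25 to 1.51 when 1 library was left out. The gene was edited in both strains, and the gene model behind these values is not given in the sources used here, so a difference in FPKM of GCR1 includes any difference in the length of the transcript. GCR2, which encodes a partner of Gcr1, had log2 fold changes of 0.04 at 6 h and -0.06 at 12 h.

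The comparison of the strains at 6 h asks for differences during growth on glucose. Single glycolytic transcripts did not pass the test at this time, and the glycolysis list was called higher in S by a small difference. CDC19 stood at 1792 ± 10.9 FPKM in S and 1332 ± 74.4 in U, a log2 fold change of 0.43, and ENO2 had 0.46 (adjusted p = 1 for both). The glycolysis list had a median of 0.14 (adjusted p = 0.023, and adjusted p = 0.957 with an estimated correlation). Its call was lost with a block of replicate number (adjusted p = 0.0675) and with the block within each time (0.182). Of its 17 members 0 were called over all genes and 0 when adjusted over the list alone. The median changed sign, from -0.047 without S 6 h replicate 1 to 0.415 without S 6 h replicate 2.

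5 features were called at 6 h, and each was listed at 0 in both libraries of 1 strain. SNR18, a small nucleolar RNA on chromosome I from 142367 to 142468, was listed at 4386 and 4361 FPKM in U and at 0 in S (adjusted p = 1.62e-06). YMR272W-A (124 FPKM in U on average, adjusted p = 0.000319) and YCR038W-A (33.7 FPKM in U on average, adjusted p = 0.000319) were also listed at 0 in S. PLS1, on chromosome XIV from 440797 to 440919, was listed at 58.8 and 50.4 FPKM in S and at 0 in U (adjusted p = 0.00131), and CPP3, which was chosen after its values were seen, at 10.1 and 8.80 FPKM in S and at 0 in U. The call of PLS1 was lost without S 6 h replicate 1 (adjusted p = 0.0638) and without S 6 h replicate 2 (0.0576), and with a pseudocount of 0.1 (0.15). Without the rows listed at 0 in any library, a setting chosen after seeing the data, limma called 0 of 6143 genes (38 at an unadjusted p under 0.05).

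5 lists were called between the strains at 6 h, each with adjusted p = 0.957 with an estimated correlation. Purine and one-carbon synthesis was lower in S, with a median of -0.47 (adjusted p = 1.17e-12) and 15 of 16 members below 0, GCV1 at -0.92. The general stress response had -0.31 (adjusted p = 0.00427), HSP12 at -0.88, and the respiratory chain -0.11 (adjusted p = 0.00789), COX7 at -0.48. When 1 library was left out, GCV1 ran from -1.70 to -0.15, HSP12 from -1.34 to -0.42 and COX7 from -0.81 to -0.16. Small nucleolar and ribosomal RNA had a median of -0.09 (adjusted p = 0.000237), and glycolysis 0.14 (adjusted p = 0.023, and 0.0675 with a block of replicate number). As at 12 h, the difference of the RNA list may reflect the selection of poly(A) RNA and not the cells. The respiratory chain call was lost with quantile normalization (adjusted p = 0.0893). Apart from SNR18, 0 members of these lists were called over all genes or adjusted over the list alone. Every one of these list calls was lost or turned when 1 library was left out: without U 6 h replicate 2 the adjusted p was 0.891 for purine synthesis and for the RNA list and 0.992 for glycolysis; without S 6 h replicate 1 it was 0.102, 0.422 and 0.954; without U 6 h replicate 1 it was 0.127 for the stress list and 0.141 for the respiratory chain; without S 6 h replicate 2 it was 0.0536 for the respiratory chain, and the stress list was higher in S (adjusted p = 7.31e-05). Without both 6 h libraries of number 1 the adjusted p was 0.747 for glycolysis and 0.677 for the RNA list. In purine synthesis the U 6 h libraries differed from each other by a median of -1.06, replicate 1 below replicate 2.

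The comparisons of 12 h with 6 h within each strain ask how each form passes from growth on glucose to the time after the diauxic shift. Both strains turned from transcripts of growth to those of the use of ethanol and of respiration. PCK1, the first enzyme of gluconeogenesis, rose from 3.88 ± 0.88 to 8286 ± 1327 FPKM in U and from 4.78 ± 0.37 to 8270 ± 2110 in S (SD, n = 2 each), log2 fold changes of 10.73 (SE 0.24) and 10.46 (SE 0.24). Cytosolic ribosomal protein transcripts fell by 2.99 on the log2 scale in U and by 3.18 in S as medians of 134 genes. Glycolytic transcripts had a median of -2.27 in U and of -0.56 in S.

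**Figure D3:**
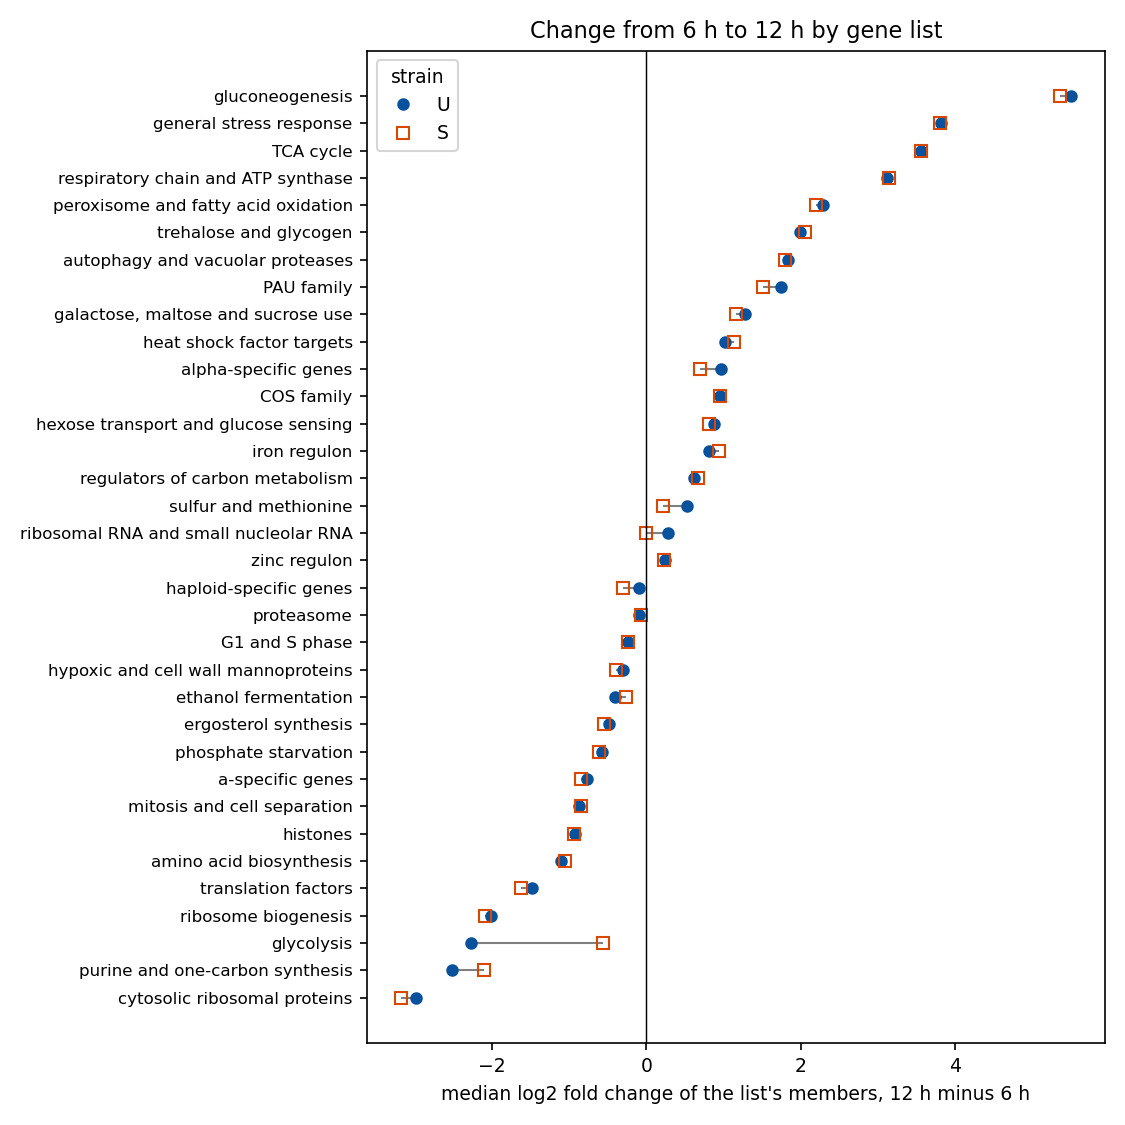
Median log2 fold change from 6 h to 12 h of the members of each of 34 gene lists in U (filled circles) and in S (open squares), with a grey line between the strains. The lists lie close together in both strains, and glycolysis lies at -2.27 in U and -0.56 in S.

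Of 6339 genes tested with limma, 3503 changed in U (2126 higher and 1377 lower at 12 h) and 3557 in S (2107 higher and 1450 lower). Of these, 2308 in U and 2345 in S changed by at least 2-fold. The median of all genes was 0.26 in U and 0.23 in S with the deposited values. With median-of-ratios scaling it was 0.02 in both, and the share of higher genes went from 60.7% to 48.5% of the calls in U and from 59.2% to 48.8% in S. With quantile normalization the share was 47.0% in U and 47.4% in S. Without U 12 h replicate 1 the count in U was 2323, and without S 12 h replicate 1 the count in S was 2317. The medians of all 20 lists called in U and of all 19 called in S kept their sign under both scalings.

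Genes for the use of non-fermentable carbon rose together in U and S. In the list for gluconeogenesis, the glyoxylate cycle and the use of ethanol, acetate and lactate, 23 of 24 members rose in each strain, with medians of 5.50 in U and 5.36 in S (5.26 and 5.15 with median-of-ratios scaling). FBP1, fructose-1,6-bisphosphatase, rose by 8.93 in U and 9.08 in S, and MLS1, malate synthase, by 10.10 and 9.98. Of the 18 TCA cycle genes 17 rose in each strain (medians 3.56 and 3.56), with SDH2, a subunit of succinate dehydrogenase, at 5.14 and 5.26 and CIT1, citrate synthase, at 4.68 and 4.76. Of the 35 genes of the respiratory chain and ATP synthase 33 rose in each (3.12 and 3.14), with NDE2 at 6.48 and 6.21 and COX7 at 3.99 and 4.32. Of the 19 peroxisome and fatty acid oxidation genes 17 rose in each (2.28 and 2.20), with POT1, a thiolase, at 4.84 and 4.54. At 6 h replicate 1 stood above replicate 2 by medians of 0.47 in U and 0.66 in S for the TCA cycle and 0.41 and 0.51 for the respiratory chain. The counts stayed the same when adjusted over the list alone. The adjusted p of these lists was between 1.93e-12 and 5.02e-06 in U and between 6.69e-13 and 3.81e-06 in S. With an estimated correlation, the adjusted p was 0.427 in U and 0.44 in S for the first and last of these lists and 0.476 and 0.532 for the others.

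Lists of general stress, storage and recycling genes were called higher at 12 h with the preset correlation. Of the 32 general stress genes 23 rose in U and 24 in S (medians 3.82 and 3.80), and SIP18, a gene of the response to drying, rose by 11.27 in U and 12.00 in S. Its level was 45708 ± 11507 FPKM in U and 46886 ± 8649 in S at 12 h (SD, n = 2 each). Autophagy and vacuolar protease genes rose in 13 and 14 of 19 cases (1.84 and 1.79), with ATG8 at 2.74 and 2.99, and trehalose and glycogen genes in 9 of 19 in each strain (1.99 and 2.05). Genes for galactose, maltose and sucrose rose in 11 and 10 of 15 cases (1.28 and 1.17), with GAL3 at 3.67 and 3.55, and those of the iron regulon in 15 and 16 of 24 (0.81 and 0.94; 0.57 and 0.73 with median-of-ratios scaling), with SIT1 at 1.93 and 2.16. When adjusted over the list alone, 14 autophagy genes and 13 sugar genes rose in U and 8 trehalose and glycogen genes in each strain, and the other counts stayed the same. Over all 6339 genes 2126 rose in U and 2107 in S. The trehalose and glycogen counts lie not far above that share, so they alone show little that is particular to this list. The adjusted p ran from 8.4e-06 for stress to 0.0437 for trehalose and glycogen in U and from 2.66e-06 to 0.0315 for the same lists in S. With an estimated correlation it was 0.577, 0.627, 0.807, 0.476 and 0.571 in U, in the order given, and 0.605, 0.631, 0.776, 0.531 and 0.532 in S. Besides the stress and trehalose lists, the autophagy list (0.42 in U and 0.77 in S) and the iron regulon (0.38 and 0.39) were higher in replicate 1 at 6 h. The heat shock factor targets, also higher in replicate 1 at 6 h, were not called as a list from 6 h to 12 h. Their medians were 1.02 in U and 1.13 in S. The trehalose and glycogen call was lost without U 6 h replicate 2 (adjusted p = 0.231), without U 12 h replicate 1 (0.0844) and without S 6 h replicate 2 (0.191), as was the iron call in U without U 6 h replicate 2 (0.0874).

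Genes of protein synthesis and of growth fell. Of 134 cytosolic ribosomal protein genes 132 fell in U and 133 in S, with RPL9A, of the large subunit, at -5.11 and -5.29 and RPS22A at -4.83 and -4.90. Of 49 ribosome biogenesis genes 47 and 48 fell (medians -2.01 and -2.09), with NOP1, the fibrillarin of yeast, at -3.36 and -3.47, and of 20 translation factors 19 fell in each strain (-1.48 and -1.63), with YEF3 at -3.66 and -3.80. Purine and one-carbon synthesis fell in 15 and 12 of 16 cases (-2.52 and -2.11), with ADE17 at -4.96 and -4.28. Amino acid biosynthesis fell in 28 of 50 in each (-1.11 and -1.05), with HIS1 at -3.54 and -3.72, while 5 members in U and 3 in S rose. At 6 h the log2 difference of replicate 1 minus replicate 2 had medians of -0.63 in U and -0.85 in S for ribosome biogenesis, -0.27 and -0.40 for translation factors, -0.77 and -0.71 for amino acid biosynthesis and -1.06 and -0.07 for purine synthesis. When adjusted over the list alone, 48 ribosome biogenesis genes fell and 6 amino acid genes rose in U, and the other counts stayed the same. The adjusted p of these lists lay between 9.44e-44 and 8.4e-06 in U and between 2.75e-43 and 1.69e-05 in S. With an estimated correlation the adjusted p was 0.571 in U and 0.605 in S for amino acid biosynthesis, 0.476 for the other lists in U, and 0.531 or 0.532 for the other lists in S.

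With the preset correlation, lists of the cell cycle and of ergosterol synthesis were called lower at 12 h in both strains. In the lists of ergosterol synthesis and of G1 and S phase most members were not called lower. Of 10 histone genes 7 fell in each strain (-0.92 and -0.94), with HTB2 at -3.13 and -3.50. Genes of mitosis and cell separation fell in 14 and 15 of 21 cases (-0.88 and -0.85), with CLB2, a mitotic cyclin, at -1.91 and -1.74, and ergosterol synthesis in 8 and 9 of 23 (-0.48 and -0.56), with ERG6 at -2.28 and -2.34. Phosphate starvation genes fell in 8 of 17 in U (median -0.58, adjusted p = 0.019, and adjusted p = 0.476 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0542), and had adjusted p = 0.0666 in S. G1 and S phase genes fell in 6 of 27 in each (-0.24 and -0.24, and -0.49 and -0.45 with median-of-ratios scaling). RNR1, a subunit of ribonucleotide reductase, had -2.27 and -2.41. This count of 6 is near the share over all 6339 genes, of which 1377 fell in U and 1450 in S. The count alone thus shows no fall particular to this list. The adjusted p ran from 8.4e-06 for mitosis to 0.0382 for G1 and S phase in U and from 2.64e-05 to 0.0284 in S. With an estimated correlation it was 0.427, 0.427, 0.484 and 0.75 in U, in the order given, and 0.44, 0.44, 0.532 and 0.703 in S. The G1 and S phase call was lost without U 6 h replicate 1 (adjusted p = 0.0583), without U 12 h replicate 1 (0.155), without S 6 h replicate 1 (0.0821) and without S 12 h replicate 1 (0.0874), as well as without both 6 h libraries of number 1 (0.0944 in U and 0.109 in S). When adjusted over the list alone, 15 of 21 mitosis genes fell in U, and the other counts of this paragraph stayed the same.

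The glycolysis list was lower at 12 h in both strains. The difference between the strains called 0 of 17 members over all genes and the list had adjusted p = 0.151 with an estimated correlation. In U 13 of 17 members fell (median -2.27, adjusted p = 6.55e-07, and adjusted p = 0.476 with an estimated correlation). ENO2 changed by -6.58 (SE 0.30), from 5721 ± 1223 to 60.6 ± 24.7 FPKM (SD, n = 2 each), CDC19 by -5.30 and TDH3 by -2.93. In S 7 of 17 members fell (median -0.56, adjusted p = 0.00645, and adjusted p = 0.605 with an estimated correlation), with ENO2 at -3.97, HXK2 at -3.03 and CDC19 at -2.17, while TDH3 had -0.23 (adjusted p = 0.513) and PGI1 had -0.46 (adjusted p = 0.0613). PGI1 was called lower in S with median-of-ratios scaling (-0.67, adjusted p = 0.0127), with the block within each time (0.0262), without U 12 h replicate 1 (0.0385) and without U 12 h replicate 2 (0.0395). The list call in S was lost without S 6 h replicate 1 (adjusted p = 0.0609), with quantile normalization (0.0986) and without both 6 h libraries of number 1 (0.13). PDC1 changed by -4.41 in U and -2.68 in S, and ADH1 by -3.81 and -1.49. The call of ADH1 in S was lost without S 12 h replicate 2 (adjusted p = 0.0527). When adjusted over the list alone, the counts were 13 of 17 in U and 7 of 17 in S.

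GCR1 had a log2 fold change of -0.63 in U (adjusted p = 0.234) and 0.07 in S (adjusted p = 0.904), and GCR2 had 0.02 in U and -0.09 in S. The values of GCR1 in S and of GCR2 in U changed sign with median-of-ratios scaling, to -0.15 and -0.23. When 1 library was left out, GCR1 ran from -0.93 to -0.34 in U and from -0.57 to 0.70 in S. GCR1 was called lower in U with the block within each time (adjusted p = 0.024), and higher in S without both 6 h libraries of number 1 (0.70, adjusted p = 0.0203).

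The difference of the time change between the strains asks which genes responded to the diauxic shift by a different amount in S and U. The glycolysis list was called with a smaller fall in S, with 0 of 17 members called over all genes and adjusted p = 0.151 with an estimated correlation. Its median difference was 1.74 on the log2 scale, with 16 of 17 members above 0, and CDC19 had the largest value among its members, 3.13 (SE 0.32, adjusted p = 0.0531). TDH3 had 2.70 (adjusted p = 0.215), PGI1 1.92 (adjusted p = 0.135) and ADH1 2.32 (adjusted p = 0.638). Of the 17 members, 0 were called over all genes (limma called 51 of 6339 genes at an unadjusted p under 0.05) and 12 when adjusted over the list alone. The list had adjusted p = 3.12e-57, and adjusted p = 0.151 with an estimated correlation. CDC19 was called with quantile normalization (3.30, adjusted p = 0.0338), without U 12 h replicate 1 (adjusted p = 0.0436) and without U 12 h replicate 2 (0.0137), ADH1 without U 12 h replicate 2 (0.0492), and the count over the list alone was 8 without U 6 h replicate 1, without S 6 h replicate 2 and without each of the S 12 h libraries.

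Over all genes 5 differed in their time change, and these were the features called at 6 h that were listed at 0 in a group: SNR18, YCR038W-A, YMR272W-A, PLS1 and CPP3. The count was 3 without U 6 h replicate 2, 13 without U 12 h replicate 2 and 2 without S 12 h replicate 2. The call of PLS1 was lost without U 6 h replicate 2 (adjusted p = 0.0528), S 6 h replicate 1 (0.232), S 6 h replicate 2 (0.258) and S 12 h replicate 2 (0.0599), as well as with a pseudocount of 0.1 (0.486), the stricter filter (0.0833) and the block within each time (0.0645). Lost too were that of YMR272W-A without U 6 h replicate 2 (0.051) and S 12 h replicate 2 (0.0603), and that of CPP3 without S 12 h replicate 2 (0.0603). Without rows listed at 0 in any library limma called 0 genes (43 at an unadjusted p under 0.05).

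Across genes, which are not independent replicates, the time changes of U and S, which share no library, had a Pearson correlation of 0.956 and a Spearman correlation of 0.965. Of the genes called, 1953 were higher in both strains (706.7 by chance), 1320 were lower in both (315.0 by chance) and 2 went opposite ways. The strain differences at 6 h and at 12 h had a Pearson correlation of 0.017 and a Spearman correlation of 0.071. YCR038W-A was called at both times, in opposite directions.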

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

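All tests of explanations in this part were chosen after the results were seen. The results are those whose change from 6 h to 12 h differed between the strains by the test of the difference.

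The glycolysis list had a smaller fall in S, with a median difference of 1.74, but 0 of 17 members were called over all genes. The difference itself is therefore not settled. With an estimated correlation the list was not called (adjusted p = 0.151). That setting called 0 lists in every comparison, so the missing call does not show that the difference is absent. In the simulated data, whose genes did not vary together, it did call a list raised by 1 (adjusted p = 0.0174 at 12 h with camera). The call with the preset correlation thus has no backing from the camera setting that estimates the correlation. A difference in library scaling is argued against, since the median of all genes differed between the strains at 12 h by -0.0400 where the list differed by 1.87. A U culture further along the whole change is also argued against. The measure was the share of the change in U by which S stood short of U at 12 h. Over the 905 other genes that changed at least 4-fold in U its median was 0.0037, with quartiles of -0.03 and 0.034. For the 11 glycolysis genes that changed as much, the median was 0.70, with shares from -0.086 to 1.31. Genes already settled by 12 h in both strains would show a share near 0 either way. A lag limited to transcripts still changing at 12 h stays open. The level of GCR1 transcript had a log2 difference of 1.58 in the same direction, which did not pass the test (adjusted p = 1) and includes any effect of the gene model. Whether the level differed is open, and a level cannot be told apart from the form of the protein when each strain has its own form. The difference, if it holds, may follow from the form of Gcr1, from its level if that differs, or from another difference between the strains, and these stay open as hypotheses.

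5 features differed in their time change and were listed at 0 in a group: SNR18 by 12.09, YCR038W-A by 10.23, YMR272W-A by 6.12, PLS1 by -5.79 and CPP3 by -3.76 on the log2 scale, values that depend on the pseudocount and are no fold. Failed estimates of short features may account for them: of rows with a mean of at least 10 FPKM, 14.9% of those shorter than 300 bp were listed at 0 in some library against 0.057% of the longer ones, and the 3 of the 5 features with a known length were at most 156 bp. Loss of the sequence from 1 strain is argued against for YCR038W-A, YMR272W-A and CPP3, which were above 0 at 12 h in the strain that listed them at 0 at 6 h. At 12 h 0 of the 5 were called in the same direction as at 6 h, 2 had the opposite sign, and YMR272W-A kept its sign (-0.84, adjusted p = 1), so a lasting difference in its level stays open. For SNR18 and PLS1, listed at 0 in all 12 h libraries, it stays open too.

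The ethanol fermentation list differed by a median of 0.0938 and a mean of 0.52 (adjusted p = 6.98e-05, and adjusted p = 0.161 with an estimated correlation), and without S 6 h replicate 1 the adjusted p was 0.0566. The purine and one-carbon list differed by 0.46 (adjusted p = 2.38e-08), with adjusted p = 0.964 without U 6 h replicate 2 and 0.076 without S 6 h replicate 1. The general stress list differed by 0.28 (adjusted p = 0.00259), with adjusted p = 0.479 without U 6 h replicate 1, 0.848 without U 12 h replicate 2 and 0.301 without S 12 h replicate 1, and it was turned to lower without S 6 h replicate 2 (0.00292). The cytosolic ribosomal proteins differed by -0.15 (adjusted p = 0.000496), with adjusted p = 0.116 without U 6 h replicate 2, 0.117 without S 6 h replicate 2 and 0.911 without S 12 h replicate 1, and were turned to higher without U 12 h replicate 2 (6.16e-10). These 3 lists had adjusted p = 0.978 with an estimated correlation.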

How the results depend on the processing

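Each comparison was repeated with 1 setting changed at a time, or 2 where rows listed at 0 were left out together with a block. Counts of genes are called genes unless stated, and the cause of a change was not tested unless the setting itself shows it.

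At 6 h, 5 genes were called between the strains. Leaving out rows listed at 0 gave 0, with and without the block of replicate number within each time, since all 5 were such rows, and keeping matched rows only gave 3. For GCR2 leaving out 1 library gave -0.0178 to 0.104, with -0.00729 without U 6 h replicate 1. SHM2, -0.75 at 6 h, ran from -1.49 to 0.00186, and YGP1, -0.92, from -1.85 to 0.00157.

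At 12 h, 8 genes were called. A block of replicate number gave 2, the block within each time 13, this block without rows listed at 0 18, a fit to the 12 h groups alone 0, leaving out both 6 h libraries of number 1 2, and leaving out 1 library 1 to 15. GCR2 ran from -0.148 to 0.0238.

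From 6 h to 12 h, a minimum absolute log2 fold change of 1 gave 2308 in U and 2345 in S, by construction fewer than the 3503 and 3557 called. Leaving out 1 library gave 2323 to 3754 in U and 2317 to 3665 in S. GCR2 in U had -0.231 with median-of-ratios scaling, -0.177 with quantile normalization and -0.0341 without the 6 h libraries of number 1, and -0.0402 to 0.0724 leaving out 1 library. GCR1 in S had -0.146 with median-of-ratios scaling, -0.108 with quantile normalization, and -0.566 to 0.701 leaving out 1 library.

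For the difference of the time change, 5 genes were called. Leaving out rows listed at 0 gave 0, with and without the block, keeping matched rows gave 3, and leaving out 1 library gave 2 to 13.

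An estimated correlation gave 0 called lists in every comparison (5 at 6 h, 6 at 12 h, 20 in U, 19 in S and 5 for the difference with the preset value). The block within each time gave 10 lists at 6 h, 10 at 12 h and 8 for the difference. Leaving out the 6 h libraries of number 1 gave 9 at 6 h and 9 for the difference. Leaving out 1 library gave 5 to 13 lists at 6 h, 6 to 13 at 12 h and 9 to 14 for the difference. A count-based test was not run, because the values are not counts.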

Other observations

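All tests of explanations in this part were chosen after the results were seen, as were the single genes named, except members of the regulator and hexose transport lists.

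Regulators of carbon metabolism and hexose transporters changed in both directions from 6 h to 12 h. Of 30 regulators 15 rose and 5 fell in U, and 16 rose and 3 fell in S. The activators of genes for non-fermentable carbon were among those that rose: SIP4 by 6.02 in U and 6.02 in S, CAT8 by 3.89 and 3.78, ADR1 by 3.72 and 3.52, and HAP4, of the activator of respiratory genes, by 3.09 and 2.61. Of 15 hexose transport and sensing genes 7 rose and 4 fell in each strain. HXT6 (7.26 and 6.96) and HXT5 (6.75 and 6.60) rose, while HXT3 (-5.71 and -5.69), a transporter of low affinity, and HXT4 (-4.95 and -5.04) fell. Neither list was called as a whole. Over all 6339 genes 2126 rose and 1377 fell in U, and 2107 rose and 1450 fell in S. The reads of HXT6 may be shared with a near copy of the gene, which was not tested, and its change kept its call in all alternatives run, at 7.05 with median-of-ratios scaling in U.

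GPI2, the upstream neighbour of GCR1, was listed at 99.8 and 92.1 FPKM in S and at 35.1 and 44.0 in U at 12 h, a log2 fold change of 1.27 (SE 0.16, adjusted p = 0.0959). It was called with quantile normalization (1.37, adjusted p = 0.0358) and with the block within each time without rows listed at 0 (0.0252). At 6 h it was listed at 50.0 and 42.8 FPKM in S and at 41.1 and 38.1 in U. GPI2 ends at 411285, 968 bp before the start of GCR1. LEU2, URA3 and MET17, which BY4741 lacks, were listed at 0 in every library. HIS3, also on the fixed list of auxotrophic marker genes of BY4741, was listed at 68.8 to 282.8 FPKM. Whether its reads came from an intact gene was not tested. The a-specific genes, which cells of the a mating type of BY4741 express, were higher in replicate 1 than in replicate 2 at 12 h. This held in all 7 cases in both strains, with medians of 1.34 in U and 1.02 in S. In S these included MFA1, listed at 543 FPKM in replicate 1 and at 0 in replicate 2. As MFA1 had at least 151 FPKM in every other library, this 0 may be a failed estimate. STE2, the pheromone receptor, was listed at 634 and 208 FPKM in U and at 522 and 256 in S.

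Heat shock transcripts were high in the 6 h replicate 1 libraries of both strains. HSP82 was listed at 1025 FPKM in replicate 1 and 23.6 in replicate 2 of U, and at 973 and 21.2 in S, and BTN2 at 960 and 11.5 and at 780 and 14.8. RNA of a 12 h culture mixed into these libraries is argued against: 24 transcripts far higher at 12 h stood there at a median of at most 0.0055 of their 12 h level, while the heat shock list would need a share of 0.645 in U and 0.644 in S. The scaling of the libraries is argued against by a median difference of at most 0.14 over all genes at 6 h, and a library batch that follows the replicate number at both times by a correlation of at most 0.085 between the replicate differences of a 6 h and a 12 h group. The handling of the cultures or of the cells at harvest is one candidate explanation that these tables do not test, and no biological explanation was tested, since a replicate is no group of the design.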
